A study of Mus musculus with 19 samples.

How the data were processed

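RNA was measured in gastrocnemius, a calf muscle, of FVB mice. Per the labels, the muscle was frozen either in weight loss maintenance (WLM) or after 24 hours of refeeding (REL), RNA was isolated with an RNeasy column kit, and libraries were made with the NuGEN Universal Plus mRNA kit. Animals were wild type (WT) or carried mCK-hLPL, human lipoprotein lipase under the muscle creatine kinase promoter. The 19 libraries form 4 groups: 5 of WT_WLM, 5 of mCK-hLPL_WLM, 4 of WT_REL and 5 of mCK-hLPL_REL. The labels do not state that each library is a separate animal, so p-values measure only the spread between these samples.

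The authors deposited 1 table of 54176 gene symbols with whole-number counts per library that had not been normalized. Per the submitters' processing notes, Salmon 0.14.2, DESeq2 1.28.1 and the builds mm10 and GRCm38 were used; their roles, the strand setting and the gene annotation are not given in the sources used here. A sheet name points to variance-stabilised values, but the totals of the columns differ and all values are whole, so the planned test on log2 values was replaced by its planned fallback for counts. A spreadsheet had turned 24 symbols into dates; those rows held 0.063% of all counts and are not named. No count was recorded in any library for 19516 rows. The WT_REL columns carry numbers that do not match the sample titles in 2 cases; those libraries are called A and B here and have no replicate number. The table has 1 row for lipoprotein lipase, the mouse gene Lpl, and none for the human transgene. Whether human reads were counted at the mouse row is not given, so that row cannot be read as a measure of the transgene.

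Total counts per library ranged from 35595030 to 51073355. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 17028. Counts were scaled with TMM factors, which ran from 0.88 to 1.166, and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) in 1 model of the 4 group means over all 19 libraries. The 6 contrasts were: genotype within each phase, refeeding within each genotype, the genotype by phase interaction, and the genotype difference averaged over phases. P-values were two-sided and adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05. Log2 changes are given ± SE, the SE being the change divided by the square root of the quasi-likelihood F. CPM values use the TMM-scaled library sizes and are given as mean ± SD.

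Before the data were examined, 36 gene lists were fixed: pathways, markers of other cell types and a sex check. The outcome of the sex check is not reported here, so sex is not shown to be balanced between the groups. The 35 pathway and cell type lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The genes named were chosen by a rule fixed at the same time: per contrast, the 10 largest rises and 10 largest falls past the threshold without provisional or pseudogene symbols (the 6 of smallest p where fewer than 6 passed), up to 4 members past the threshold per list, or the 2 of smallest p where a list passed without any, and 9 further genes including Lpl in every contrast. Single genes between genotypes were also tested with an exact permutation test, two-sided, on log2 CPM with a prior count of 2. Lists of liver, lymph node, denervation and branched-chain amino acid genes were added after the data were seen. Coordinates are from GENCODE M21 on GRCm38, the build in the notes; 52503 symbols matched its names. Replicates of 1 group were compared pairwise with a chi-square per gene, and the smallest of 36 values was 24.07 per degree of freedom, so no pair agreed within sampling noise.

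The method was tested on simulated data in which known genes were changed in counts drawn from the real means, library sizes and dispersions. For the genotype difference in WLM, 63.3% of 49 genes changed by 1 on the log2 scale and 30.6% of 98 changed by 0.5 were recovered, and 3.6% of calls were false. For the interaction, 52.1% of 48 and 4% of 100 were recovered, and 5.3% of calls were false. Genes were drawn independently of each other, and no simulated library carried transcripts of other tissues. These rates may therefore not hold for the real libraries. Alternatives covered filters, scaling, moderation, library weights, DESeq2 1.42.0, the 2 groups alone, a replicate block and each library left out. Others used libraries or scores chosen after the data were seen. The replicate block used the 17 numbered libraries, which leaves 2 in WT_REL.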

Results

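Gene expression was compared in gastrocnemius muscle of wild-type mice and of mice with muscle overexpression of human lipoprotein lipase, an enzyme that releases fatty acids from circulating triglyceride. The series title concerns weight regain and energy expenditure. Muscle came from weight loss maintenance or from the first day of regain, after 24 hours of refeeding. Total counts per library ran from 37444398 to 51073355 in WT_WLM (n = 5), from 44154004 to 49324746 in mCK-hLPL_WLM (n = 5), from 36255174 to 49025261 in WT_REL (n = 4) and from 35595030 to 50558640 in mCK-hLPL_REL (n = 5).

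The transgene itself has no row in the table. Mouse Lpl (chromosome 8, 68880491 to 68907448, plus strand, GRCm38) was measured at 650 ± 78.9 CPM (SD, n = 5) in WT_WLM and 729 ± 68.3 CPM (SD, n = 5) in mCK-hLPL_WLM. It was at 674 ± 121 CPM (SD, n = 4) in WT_REL and 808 ± 102 CPM (SD, n = 5) in mCK-hLPL_REL. The mean log2 CPM differed by 0.169 in WLM (exact permutation p = 0.119, two-sided, adjusted p = 0.381 over 18 tests) and by 0.273 in REL (exact permutation p = 0.127, adjusted p = 0.381). The same test on Ppara, Ppard, Ppargc1a, Pdk4, Ucp3, Cd36, Angptl4 and Sln gave no adjusted p under 0.05 in either phase. The smallest p the design allows is 0.00794, so no gene could pass on its own after adjustment over 18 tests, however large its difference. The lack of a pass therefore says little about these genes. The genotype labels could not be checked at the transgene.

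**Figure D1:**
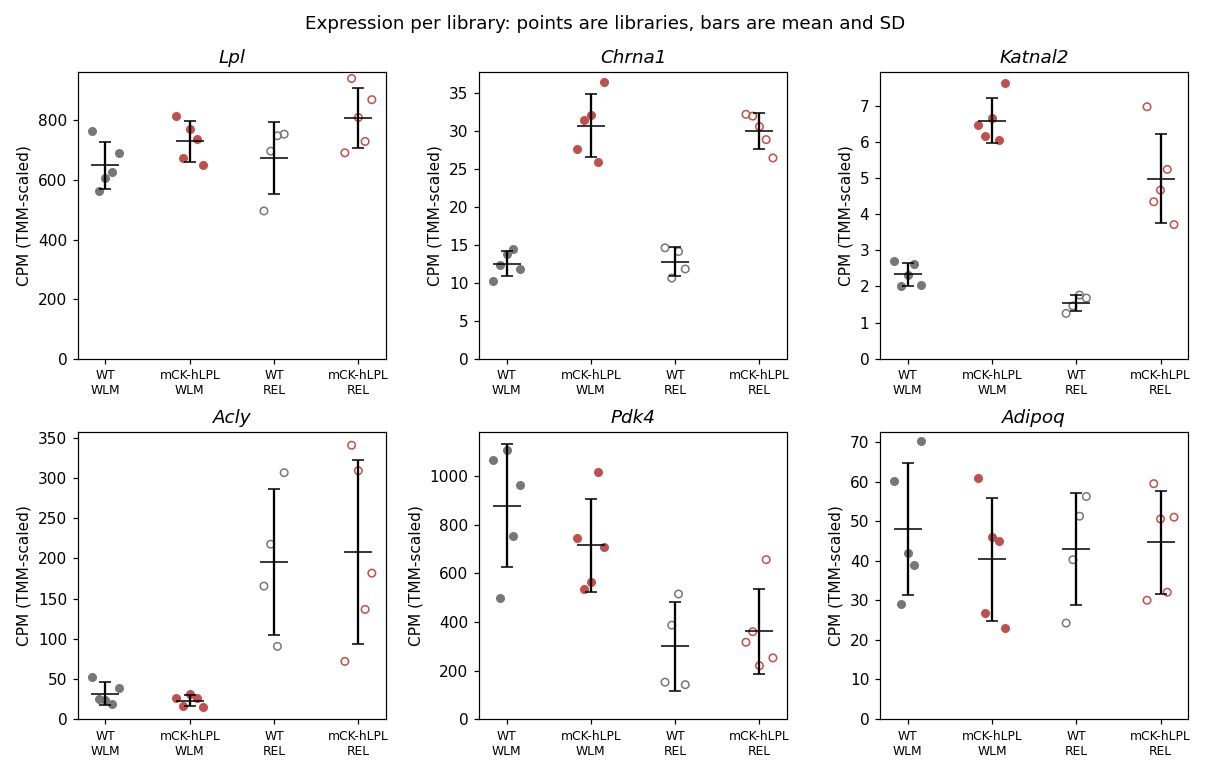
CPM per library (vertical axes, from 0) of Lpl, Chrna1, Katnal2, Acly, Pdk4 and Adipoq in the 4 groups (horizontal axes), with each point 1 library and bars for the mean and SD. Chrna1 lies near 30 CPM in both mCK-hLPL groups and near 12.5 CPM in both wild-type groups, whereas Acly separates the refed groups from the others.

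The first comparison asks which transcripts differed between genotypes during weight loss maintenance. Chrna1, the alpha subunit of the muscle acetylcholine receptor (chromosome 2, 73563215 to 73580338, minus strand), was at 30.6 ± 4.13 CPM in mCK-hLPL_WLM (SD, n = 5) and 12.5 ± 1.67 CPM in WT_WLM (SD, n = 5), a log2 difference of 1.29 ± 0.11 (SE; edgeR adjusted p = 7.31e-06). Katnal2, a katanin-like protein (chromosome 18, 76977148 to 77047308, minus strand), was higher by 1.49 ± 0.15 (adjusted p = 3.66e-05). Ostn, which encodes the secreted peptide osteocrin, was higher by 0.99 ± 0.14 (adjusted p = 0.00737), and Fbp2, the muscle fructose bisphosphatase, by 0.72 ± 0.12 (adjusted p = 0.0284). Trnp1 was lower, with a log2 difference of -1.83 ± 0.3 (adjusted p = 0.0284). In all, 5 of 17028 genes passed, 4 higher and 1 lower, and 828 had an unadjusted p under 0.05, against 851 from chance alone. DESeq2 called 22, which included these 5. The sixth by p, Maged2, was at 0.52 ± 0.09 (adjusted p = 0.0709). Chrna1, Katnal2 and Ostn kept their calls without any 1 library, whereas with the replicate block, or with only the 2 groups compared, 2 genes were called and Ostn was not (adjusted p = 0.0795 and 0.174). The call of Fbp2 ended (adjusted p from 0.0545 to 0.137) without WT_WLM replicate 1, 2, 3 or 4, mCK-hLPL_WLM replicate 1, 2, 4 or 5, or WT_REL replicate 1. The call of Trnp1 ended (adjusted p from 0.0521 to 0.154) without WT_WLM replicate 1, 3 or 4, any mCK-hLPL_WLM library, WT_REL replicate 1 or mCK-hLPL_REL replicate 1. In all, 3 genes were called without mCK-hLPL_WLM replicate 1, 2 or 5 or without WT_REL replicate 1.

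Among the lists, camera placed 6 lower in mCK-hLPL_WLM: immediate early genes, glucocorticoid-responsive genes, heat shock proteins, fatty acid synthesis, endothelial markers and T, B and plasma cell markers. No single member of these passed. None of the 35 lists passed with an estimated correlation, where the smallest adjusted p = 0.863, nor with fry (smallest adjusted p = 0.901). The added lymph node list went the same way as the T, B and plasma cell markers (median -1.27 over 9 members against -1.18), and its transcripts summed to 56.5 and 58.5 CPM in WT_WLM replicates 1 and 5 and 44.4 CPM in mCK-hLPL_WLM replicate 3. Without each of these in turn its median was -0.47, -0.35 and -4.71, over the 4 members still tested. Without these 3 libraries, a setting chosen after the data were seen, 12 lists passed by camera. Of the heat shock proteins, 6 of 18 were lower when adjusted over the list alone, led by Hspa1b at -1.32 ± 0.37 (adjusted p = 0.651 over all genes) and Hspa1a at -1.45 ± 0.44, genes with near-identical sequence whose counts are uncertain. The other 5 lists had no member past the threshold when adjusted over the list alone.

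On the first day of regain, Katnal2 and Chrna1 were again higher in mCK-hLPL. Katnal2 was at 4.99 ± 1.24 CPM (SD, n = 5) against 1.54 ± 0.228 CPM (SD, n = 4) in wild type, a log2 difference of 1.69 ± 0.16 (edgeR adjusted p = 2.59e-05). Chrna1 was at 30 ± 2.39 CPM against 12.8 ± 1.88 CPM, a difference of 1.23 ± 0.12 (adjusted p = 2.59e-05). These 2 were all the genes called by edgeR, and both kept their calls without any 1 library. The replicate block ended the call of Chrna1 (1.21, adjusted p = 0.156) and called 1 gene. It used the 17 numbered libraries, 2 of them in WT_REL. In the same 17 libraries without the block, a setting chosen after the data were seen, Chrna1 kept its call. Fewer samples alone thus did not end that call. Library weights called 9, DESeq2 27, and the fat cell score as a covariate (chosen after the data were seen) 4. By edgeR 743 genes had an unadjusted p under 0.05, against 851 from chance alone. Next by p came Chrne, the epsilon subunit of the adult acetylcholine receptor, at 0.76 ± 0.14, Oxct1, the ketone-body enzyme, at -0.52 ± 0.1, 2310065F04Rik at -0.75 ± 0.14, and Stxbp4 at -0.46 ± 0.09, each with adjusted p = 0.0923. Camera placed 11 lists past the threshold, 4 higher and 7 lower, among them interferon response (higher, median log2 difference 0.39 over 25 members) and slow and oxidative fibre genes (lower, median -0.25 over 15 members). With an estimated correlation these had adjusted p = 0.425 and adjusted p = 0.507, and no list passed. No member of either list passed over all genes; adjusted over the list alone, 2 slow-fibre genes were lower and no interferon gene passed. Erythroid markers were also placed higher (median 1.03 over 6 members, adjusted p = 0.599 with an estimated correlation). Hemoglobin transcripts summed to 4681 ± 3911 CPM in mCK-hLPL_REL and 2306 ± 1554 CPM in WT_REL; without mCK-hLPL_REL replicate 1, at 11525.1 CPM, the former were 2969 ± 936.4 CPM (SD, n = 4).

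Averaged over both phases, 36 genes differed between genotypes, 21 higher and 15 lower in mCK-hLPL. Among those higher were Chrna1 at 1.26 ± 0.08 (edgeR adjusted p = 5.2e-08), Chrne at 0.72 ± 0.09 (adjusted p = 0.00109), and Ache, which encodes acetylcholinesterase, at 0.58 ± 0.1 (adjusted p = 0.0124). Katnal2 was higher by 1.59 ± 0.11 (adjusted p = 8.56e-08), Ostn by 0.8 ± 0.1, Hpgd by 0.73 ± 0.14, Fbp2 by 0.69 ± 0.09, Sema3a by 0.62 ± 0.12, Gadl1 by 0.57 ± 0.09 and Ccl25 by 0.52 ± 0.08. The largest falls among genes with full symbols were Trnp1 at -1.61 ± 0.22, Lrtm2 at -1.06 ± 0.21, Epop at -0.93 ± 0.15, Adra1a at -0.67 ± 0.11, Smad3 at -0.47 ± 0.09, Ccdc85c at -0.46 ± 0.09, Oxct1 at -0.46 ± 0.07, Adhfe1 at -0.4 ± 0.06, Ivd at -0.38 ± 0.07 and Mical2 at -0.37 ± 0.07. Chrne lies on chromosome 11 (70614883 to 70619216, minus strand) and Ache on chromosome 5 (137287519 to 137294466, plus strand). DESeq2 called 84 genes, which included all 36. A minimum log2 change of 0.5 left 19 and the replicate block 6. Of settings chosen after the data were seen, the same 17 libraries without the block gave 10, the fit without the 3 libraries with lymph node transcripts 16, without the 3 with most liver transcripts 17, and the red cell score as a covariate 23. Camera placed 9 lists past the threshold and none with an estimated correlation (smallest adjusted p = 0.783). Of the 20 genes named here, 13 kept their calls without any 1 library. The others were Hpgd (lost without 9 of the 19 libraries in turn), Sema3a (14), Lrtm2 (15), Smad3 (10), Ccdc85c (16), Ivd (4) and Mical2 (8), with adjusted p of at most 0.128 where a call was lost. Without WT_REL replicate A the count was 20, without WT_REL replicate 2 it was 22 and without mCK-hLPL_REL replicate 2 it was 23.

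Far more transcripts differed between REL and WLM. Changes with refeeding below mean differences between these phases. The libraries with most lymph node transcripts were all WLM, and those with most liver transcripts were all REL. Tissue content and refeeding are thus not fully separated. In wild type, 831 genes differed between REL and WLM, 448 higher and 383 lower, with 3513 at an unadjusted p under 0.05. The count was 1372 by DESeq2, 1276 with library weights, 492 with no low-count filter, 425 with a minimum log2 change of 0.5 and 32 with the replicate block. It was 166 in the same 17 libraries without the block, a setting chosen after the data were seen. Of genes without provisional symbols, Ncan, a proteoglycan core protein, rose from 0.378 ± 0.197 CPM (SD, n = 5) to 7.52 ± 1.89 CPM (SD, n = 4), a log2 change of 4.29 ± 0.46 (edgeR adjusted p = 7.45e-05). Angptl8, an insulin-responsive inhibitor of lipoprotein lipase, rose by 4.3 ± 0.67 from 0.0666 CPM. Mogat2 rose by 3.76 ± 0.71, Adcy10 by 3.03 ± 0.58, Oxtr by 3 ± 0.43, Nmrk2 by 2.81 ± 0.37, Pkp1 by 2.73 ± 0.68, Hephl1 by 2.69 ± 0.56, the fructose transporter Slc2a5 by 2.68 ± 0.75 and Acly, which makes cytosolic acetyl-CoA, by 2.62 ± 0.42. The largest falls were Cacna1i at -2.87 ± 0.53, Cyp2e1 at -2.64 ± 0.49, Nnat at -2.08 ± 0.44, Acsm5 at -2.04 ± 0.44, Mycl at -1.96 ± 0.41, the mitochondrial carrier Slc25a34 at -1.92 ± 0.2, B4galnt4 at -1.86 ± 0.43, Tgtp1 at -1.83 ± 0.45, Ido1 at -1.78 ± 0.45 and Tmem82 at -1.74 ± 0.37. Tgtp1 has a near-identical copy, so its count is uncertain.

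Cholesterol synthesis and LDL receptor genes rose with refeeding in wild type: 16 of 22 were higher and none lower, 18 and 2 when adjusted over the list alone, with Sqle at 1.57 ± 0.25, Nsdhl at 1.13 ± 0.15, Cyp51 at 1.02 ± 0.15 and Acat2 at 0.9 ± 0.22. This list alone kept its call with an estimated correlation (adjusted p = 0.0416). Fry, which tests whether the genes of a list move on balance and does not compare them with other genes, called 5 lists (smallest adjusted p = 0.000255): this one, fatty acid synthesis, fatty acid oxidation, the fasting, FOXO and proteolysis list and ribosome biogenesis. Fatty acid synthesis genes were higher in 7 of 20 (17 over the list alone, where 1 was lower), led by Acly and by Scd2 at 1.97 ± 0.23, with adjusted p = 0.0905 with an estimated correlation. Fatty acid oxidation genes were lower in 9 of 29 and higher in none (16 lower over the list alone; adjusted p = 0.0905 with an estimated correlation). Among them Pdk4, which restrains pyruvate oxidation, was at -1.56 ± 0.38, Acot2 at -1.27 ± 0.16, Acot1 at -1.25 ± 0.18 and Ucp3 at -1.19 ± 0.32; Acot1 and Acot2 are paralogs whose counts are uncertain. In the fasting, FOXO and proteolysis list 6 of 25 were lower, including Fbxo32 at -1.12 ± 0.3 and Eif4ebp1 at -0.9 ± 0.12, and 1, Nmrk2, was higher (13 and 3 over the list alone; adjusted p = 0.0905 with an estimated correlation). Of 25 genes of triglyceride uptake and storage, 6 were lower, among them Cd36 at -0.52 ± 0.11 and Plin5 at -1.07 ± 0.17, and 2 were higher, Agpat2 at 1.76 ± 0.31 and Plin2 at 0.87 ± 0.2 (adjusted p = 0.64 with an estimated correlation). Collagen and extracellular matrix genes were higher in 5 of 31 (12 over the list alone; adjusted p = 0.554 with an estimated correlation), with Col1a1 at 1.77 ± 0.41. Markers of other cell types rose with them by camera: fibroblast (median 0.32), smooth muscle and pericyte (0.27), Schwann cell (0.42) and erythroid markers (1.14), none with an estimated correlation (adjusted p from 0.554 to 0.622). Circadian clock genes were higher in 5 of 20, among them Dbp at 1.11 ± 0.19 and Nr1d1 at 1.05 ± 0.24, and lower in 1 (6 and 4 over the list alone); the list did not pass by camera (adjusted p = 0.109). Ribosome biogenesis genes were lower in 7 of 30, with Npm1 at -0.58 ± 0.12 (9 over the list alone; adjusted p = 0.372 with an estimated correlation). The fat cell marker Adipoq, chosen for the plot after its values were seen, was not past the threshold (-0.16, adjusted p = 0.822). Lymph node transcripts were highest in WT_WLM replicates 1 and 5 and in mCK-hLPL_WLM replicate 3. A smaller amount, 3.96 CPM, was in mCK-hLPL_REL replicate 2, which stays in the fit without those libraries. Liver transcripts summed to 176 CPM in WT_REL B. Without the 3 libraries with lymph node transcripts, 316 genes were called, and without the 3 with most liver transcripts, 462. With the red cell score as a covariate 233 were called. These settings were chosen after the data were seen. Erythroid markers were themselves higher in REL (median 1.14), so that covariate can also take up refeeding changes. Common median scaling moved the share of higher genes from 53.9% to 46.8%. Of 79 named genes past the threshold, 33 kept their calls without any 1 library. Of those printed here, 15 lost theirs, with adjusted p of at most 0.165. Hephl1, Plin2, Npm1 and Cd36 did so without WT_REL replicate B, and Nr1d1 without WT_REL replicate 1. Col1a1 did so without WT_WLM replicate 3 or WT_REL replicate 1 or 2, and B4galnt4 without WT_REL replicate 1, 2 or B. Pkp1 did so without WT_WLM replicate 1 or 3 or WT_REL replicate A or B, and Pdk4 without WT_WLM replicate 1 or 3 or WT_REL replicate 1 or B. Tgtp1 did so without WT_WLM replicate 5 or WT_REL replicate 1, A or B, and Ido1 without these or WT_WLM replicate 3. The calls of Ucp3, Fbxo32 and Acat2 ended without WT_REL replicate 1, 2 or B, and without WT_WLM replicate 1, 3 or 5 for Ucp3, 1, 3 or 4 for Fbxo32 and 2, 3 or 4 for Acat2. That of Slc2a5 ended without WT_WLM replicate 2, 3 or 4, WT_REL replicate 1, 2 or B, mCK-hLPL_WLM replicate 1 or 4 or mCK-hLPL_REL replicate 3 or 4. The count was 257 without WT_REL replicate B, 325 without WT_REL replicate 1, 378 without WT_REL replicate 2, 421 without WT_WLM replicate 3 and 517 without WT_WLM replicate 1.

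In mCK-hLPL, 1387 genes differed between REL and WLM, 700 higher and 687 lower, with 4162 at an unadjusted p under 0.05. The count was 793 with no low-count filter, 628 with only the 2 groups compared, 594 with a minimum log2 change of 0.5 and 484 with the replicate block. Without provisional symbols, the largest rises were Ncan at 4.49 ± 0.45, Mogat2 at 4.35 ± 0.7, Angptl8 at 3.98 ± 0.64, Adcy10 at 3.56 ± 0.57, Slc2a5 at 3.24 ± 0.75, Acly at 3.18 ± 0.42, Hephl1 at 2.96 ± 0.54, Oxtr at 2.92 ± 0.42, Mal2 at 2.75 ± 0.63 and Elovl6 at 2.65 ± 0.53. The largest falls were Nnat at -2.36 ± 0.41, Vnn1 at -1.86 ± 0.43, Chrna2 at -1.81 ± 0.41, Mycl at -1.76 ± 0.37, Cyp2e1 at -1.69 ± 0.44, Gpr179 at -1.67 ± 0.39, Acsm5 at -1.4 ± 0.4, Fkbp5 at -1.4 ± 0.39, Kcnip2 at -1.37 ± 0.41 and Prima1 at -1.35 ± 0.29 (edgeR adjusted p between 6.2e-05 and 0.043 for these 20). Fatty acid synthesis genes were higher in 15 of 20 (17 over the list alone, 1 lower), among them Fasn at 2.5 ± 0.52 and Tkt at 2.15 ± 0.39, with adjusted p = 0.106 with an estimated correlation. Cholesterol genes were higher in 16 of 22 and lower in 2 (19 and 2 over the list alone; adjusted p = 0.0549 with an estimated correlation). Fatty acid oxidation genes were lower in 13 of 29 (21 over the list alone; adjusted p = 0.114 with an estimated correlation), with Mlycd at -0.82 ± 0.1 and Hadhb at -0.42 ± 0.08. Citric acid cycle genes were lower in 6 of 24, including Sucla2 at -0.43 ± 0.08, and higher in 1, Pcx, at 0.79 ± 0.2. Over the list alone these were 13 and 1, and camera gave adjusted p = 0.324 with an estimated correlation. Slow fibre (median -0.34), fast fibre (-0.16) and oxidative phosphorylation genes (-0.12) fell with them by camera. None of these passed with an estimated correlation (adjusted p from 0.324 to 0.531). Pdk4 was at -0.99 ± 0.35 (adjusted p = 0.086) and Ucp3 at -0.67 ± 0.29 (adjusted p = 0.158). Erythroid markers were higher in 3 of 6 (6 over the list alone; adjusted p = 0.324 with an estimated correlation), and hemoglobin transcripts were 4681 ± 3911 CPM in REL (SD, n = 5) and 1542 ± 882.9 CPM in WLM (SD, n = 5), or 2969 ± 936.4 CPM in REL without mCK-hLPL_REL replicate 1 (SD, n = 4). Collagen and extracellular matrix genes were higher in 6 of 31 (11 over the list alone; adjusted p = 0.508 with an estimated correlation), with Col3a1 at 1.43 ± 0.35. Fibroblast (median 0.31), macrophage (0.46), endothelial (0.19), Schwann cell (0.38) and smooth muscle and pericyte markers (0.29) rose with them by camera, none with an estimated correlation (adjusted p = 0.531 each). Fat cell markers were higher in 2 of 14, Thrsp at 1.89 ± 0.38 and Adig at 1.02 ± 0.3 (4 over the list alone; adjusted p = 0.531 with an estimated correlation). TMM factors were 0.88 to 1.013 in WLM and 1.007 to 1.143 in REL, and common median scaling moved the share of higher genes from 50.5% to 35%. Of 98 named genes past the threshold, 60 kept their calls without any 1 library. Of those printed here, 7 lost theirs, with adjusted p of at most 0.108. Col3a1 did so without mCK-hLPL_WLM replicate 2 or 3 or mCK-hLPL_REL replicate 2. Cyp2e1 did so without mCK-hLPL_WLM replicate 3 or 4 or mCK-hLPL_REL replicate 2 or 3, and Pcx without mCK-hLPL_WLM replicate 2 or 5 or mCK-hLPL_REL replicate 2 or 3. Fkbp5 did so without mCK-hLPL_WLM replicate 3 or 4 or mCK-hLPL_REL replicate 1, 2, 3 or 5, and Acsm5 without mCK-hLPL_WLM replicate 1, 2, 3 or 4 or any mCK-hLPL_REL library. Adig did so without mCK-hLPL_WLM replicate 2, 3, 4 or 5, mCK-hLPL_REL replicate 2, 3 or 5 or WT_REL replicate 2 or A. Kcnip2 did so without mCK-hLPL_WLM replicate 2, 3, 4 or 5, mCK-hLPL_REL replicate 1, 2, 4 or 5 or WT_REL replicate 2, A or B. The count was 674 without mCK-hLPL_WLM replicate 3, 678 without mCK-hLPL_REL replicate 2, 776 without mCK-hLPL_WLM replicate 2, 778 without mCK-hLPL_WLM replicate 5 and 796 without mCK-hLPL_REL replicate 3. Without the 3 libraries with lymph node transcripts it was 608, and 1573 without the 3 with most liver transcripts. It was 101 with the red cell score as a covariate and 520 with the fat cell score. These 4 settings were chosen after the data were seen. Erythroid markers (median 1.68) and fat cell markers (0.52) were themselves higher in REL, so both covariates can also take up refeeding changes. Fry called 10 lists (smallest adjusted p = 0.000162, for the cholesterol list).

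**Figure D2:**
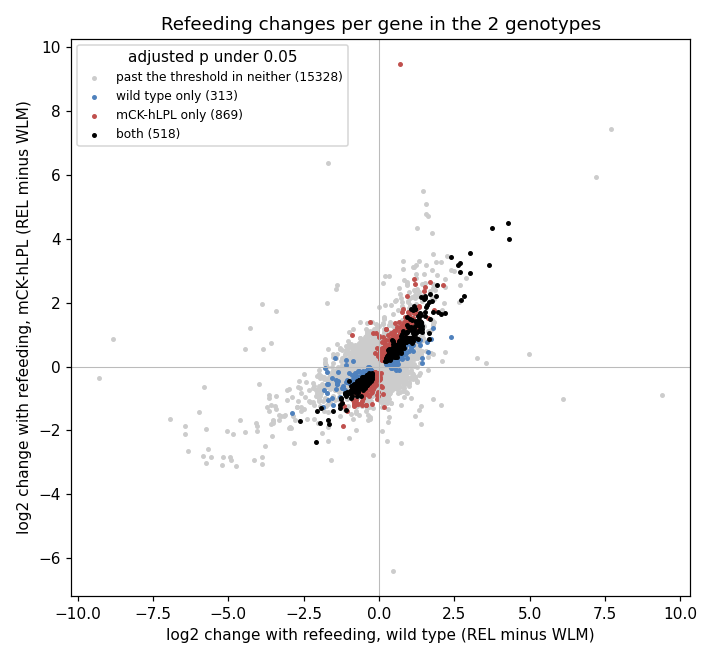
Log2 change with refeeding per gene in wild type (horizontal axis) and in mCK-hLPL (vertical axis), 1 point per tested gene, coloured by where adjusted p was under 0.05. The genes called in both genotypes, 280 higher and 238 lower, lie at the upper right and lower left.

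The refeeding changes of the genotypes, which share no library, had Pearson r = 0.594 and Spearman rho = 0.6 across 17028 genes, which are not independent replicates (r from 0.412 to 0.616 without any 1 library). With no low-count filter r was 0.187, but over every row with a count in any library, a wider set than these genes. It was 0.278 with the replicate block and 0.269 for the same 17 libraries without the block, the last chosen after the data were seen. Both genotypes called 280 rises, where independent lists would share 18.4, and 238 falls, where they would share 15.5; no gene was called in opposite directions. The genotype differences of the phases had r = -0.009 (from -0.114 to 0.078 without any 1 library) and rho = 0.105, and shared Chrna1 and Katnal2 among calls.

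The interaction asks whether refeeding acted differently in the genotypes. By edgeR 0 genes passed, and 403 had an unadjusted p under 0.05, against 851 from chance alone. DESeq2 called 2, and 1 gene passed by edgeR without WT_WLM replicate 4. In the simulation 4% of 100 genes changed by 0.5 were recovered for this contrast, so few calls do not show that the genotypes responded alike. For Acly the difference of the changes was 0.56, for Fasn 0.97 and for Pdk4 0.57 ± 0.51, each with adjusted p = 1. Trim30a, an interferon-induced gene, was among the 6 of smallest p at 0.69 ± 0.17 (adjusted p = 1). Camera placed 11 lists past the threshold, with the interferon response the furthest (median difference 0.5 over 25 members), and none with an estimated correlation (smallest adjusted p = 0.609) or with fry (smallest adjusted p = 0.871). The T, B and plasma cell markers were among the 11 (median 1.72), and the added lymph node list went the same way (median 2.74 over 9 members). The lymph node median was 1.87 without WT_WLM replicate 1 and 1.64 without WT_WLM replicate 5. It was 6.07 without mCK-hLPL_WLM replicate 3 and 1.87 without mCK-hLPL_REL replicate 2, each over the 4 members still tested. Without the 3 libraries with lymph node transcripts the lymph node median was 1.23 over the 3 members still tested and 5 lists passed. That fit kept mCK-hLPL_REL replicate 2, with 3.96 CPM of lymph node transcripts. With the fat cell score as a covariate 6 lists passed. Both settings were chosen after the data were seen. The larger count of refeeding genes in mCK-hLPL is therefore not shown to be a difference between genotypes for any gene by edgeR.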

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

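The tests of fat cells, of loss of nerve contact, of an insertion acting on neighbouring genes and of the neighbours of Katnal2, and the lists of liver and lymph node transcripts, were chosen after the results were seen.

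Of 120 groups of values screened (30 measures in 4 groups), 18 held a library far from the rest of its group, where chance gives about 6. Genes with a count numbered 22386 in WT_WLM 3. The TMM factor of WT_REL B was 1.166. Mitochondrial transcripts took 21.3% in mCK-hLPL_REL 2, and the 10 most abundant genes 28.02% in mCK-hLPL_REL 4. Hemoglobin transcripts were 3076.8 CPM in mCK-hLPL_WLM 1 and 11525.1 CPM in mCK-hLPL_REL 1. Liver transcripts summed to 35.07 CPM in mCK-hLPL_WLM 4 and 176.33 CPM in WT_REL B. Lymph node transcripts summed to 44.44 CPM in mCK-hLPL_WLM 3 and 3.96 CPM in mCK-hLPL_REL 2, where the mean log2 CPM of T, B and plasma cell markers was 2.235 and -0.268. The mean log2 CPM was -1.574 for neutrophil markers in WT_WLM 5 and 4.772 for smooth muscle markers in WT_WLM 1. The log2 CPM was 4.144 for Ppard in WT_WLM 2, 7.935 for Cd36 in WT_REL A, and 8.114 for Cd36 and 0.892 for Sln in mCK-hLPL_REL 2.

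For 11 lists the change with refeeding differed between genotypes by camera with a preset correlation. It was higher in mCK-hLPL for interferon response (adjusted p = 7.36e-16), heat shock proteins (0.000197), endothelial markers (0.00109), unfolded protein response and adipocyte markers (0.0118 each) and T, B and plasma cell markers (0.015). It was lower for slow fibre (0.000466), tendon (0.00731) and fast fibre genes (0.00993), citric acid cycle and circadian clock genes (0.0118 each). With an estimated correlation the adjusted p ran from 0.609 to 0.72, so none passed.

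The rise of fatty acid synthesis genes with refeeding was set against fat cells within the muscle. More fat cells in refed samples would raise fat cell markers at least as much, but the synthesis score rose by 0.91 more than that of 13 markers, without the marker Thrsp that is also a synthesis gene, in wild type (exact permutation p = 0.0159) and by 0.87 more in mCK-hLPL (exact permutation p = 0.00794), which argues against it. The marker score itself rose by 0.13 in wild type and 0.41 in mCK-hLPL. Adipoq was at 48 CPM in WT_WLM, 43 CPM in WT_REL, 40.4 CPM in mCK-hLPL_WLM and 44.6 CPM in mCK-hLPL_REL, and Cfd at 174, 127, 148 and 149 CPM. Adipoq and Cfd do not stand for the whole list of 14 fat cell markers. Its median change was 0.11 in wild type and 0.52 in mCK-hLPL. Adjusted over the list alone, 4 markers were higher and 0 lower in mCK-hLPL. Within groups the synthesis score followed the fat cell score over 19 libraries (r = 0.74, permutation p = 0.00199; rho = 0.75, permutation p = 0.00184; r = 0.78 without the 2 libraries farthest from the median). Transcripts of fat cells inside the muscle samples may thus be a source of part of the signal, as a hypothesis, with refeeding open as the biological explanation and muscle fibres as the source not tested.

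Higher Chrna1, Chrne, Ache and Katnal2 in mCK-hLPL were set against loss of nerve contact. The other 13 genes of the denervation list had a median log2 difference of -0.08 with an upper quartile of 0.16, and 0 reached 0.5, which argues against it. The 4 genes lie on 4 chromosomes, so 1 insertion acting on neighbouring genes does not account for them as a set. By edgeR 0 of the 14 tested genes within 1 Mb of Katnal2 passed averaged over phases (largest absolute log2 difference 0.26, smallest adjusted p = 0.644). An insertion or linked segment acting on Katnal2 alone and a genotype effect cannot be told apart for Katnal2, since its neighbours would not show it, and a genotype effect stays open, untested, for the other genes.

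More genes were called by refeeding in mCK-hLPL (1387) than in wild type (831), with 1 more library in the refed mCK-hLPL group. With 1 of those left out the median count was 967, from 678 to 1705, and 2 of the 5 were under the wild-type count, so library number and genotype cannot be told apart here.

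Other splits of the same libraries were counted, 100 per comparison with the real one included. For refeeding in wild type (831, highest other 202) only the real split called as many genes. The same held for refeeding in mCK-hLPL (1387, highest other 492). A share of 1 in 100 is the smallest these splits allow and was not adjusted for the comparisons made. It argues against chance as the whole account without strictly excluding it. For genotype in REL 4 splits called as many (2, highest other 64), and for the average over phases 2 (36, highest other 1771). Counts this high were uncommon among the splits, but in both comparisons at least 1 split other than the real one reached them. The shares were not adjusted for the several comparisons made, so chance is not firmly excluded for these counts. For genotype in WLM 17 splits called as many as 5 (highest other 259), so chance is not excluded for that count. This concerns the count and not single genes: Chrna1 and Katnal2 were called in both phases, which share no library. For the interaction all 100 called as many (0, highest other 1). Every split reaches a count of 0, so this comparison says nothing about chance. The splits with 259, 64 and 1771 genes call several times the real counts, which points to a structure of the samples; what those splits separate was not tested.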

How the results depend on the processing

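The settings without the libraries with lymph node or liver transcripts, with a fat or red cell score as a covariate, with voom and TMM, with the stricter filter on CPM, and with 17 libraries and no block were chosen after the results were seen.

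For the genotype difference in WLM (5 genes), the fit of only the 2 groups compared and the replicate block each gave 2, DESeq2 22, which included the 5, and the fit without the 3 libraries with lymph node transcripts 3; with 1 library left out the count ran from 3 to 7. For the genotype difference in REL (2 genes), library weights gave 9, the block 1, DESeq2 27 and the fat cell covariate 4, and leaving out 1 library gave 2 to 3. Katnal2 kept its call in both phases under every setting run, and Chrna1 did except in REL under the block (1.21, adjusted p = 0.156). For the average over phases (36 genes), a minimum log2 change of 0.5 gave 19, the block 6, the same 17 libraries without the block 10, DESeq2 84, the fit without lymph node libraries 16, without liver libraries 17, and the red cell covariate 23. Leaving out 1 library gave 20 to 42, with 20 without WT_REL replicate A, 22 without WT_REL replicate 2 and 23 without mCK-hLPL_REL replicate 2. For the interaction 0 genes passed by edgeR, and 403 had an unadjusted p under 0.05, against 851 from chance alone. DESeq2 called 2, and leaving out 1 library gave 0 to 1, the 1 without WT_WLM replicate 4. Where a setting drops libraries or asks for a minimum change, fewer samples or a stricter threshold are part of it; otherwise the cause was not tested.

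For refeeding in wild type (831 genes), the minimum change gave 425, no low-count filter 492, library weights 1276, the block 32, the same 17 libraries without it 166, DESeq2 1372, no lymph node libraries 316, no liver libraries 462 and the red cell covariate 233. Leaving out 1 library gave 257 to 1027, with 257 without WT_REL replicate B, 325 without WT_REL replicate 1, 378 without WT_REL replicate 2, 421 without WT_WLM replicate 3 and 517 without WT_WLM replicate 1. For refeeding in mCK-hLPL (1387 genes), the minimum change gave 594, no filter 793, only the 2 groups 628, the block 484, no lymph node libraries 608, the fat cell covariate 520 and the red cell covariate 101. Leaving out 1 library gave 674 to 1705, with 674 without mCK-hLPL_WLM replicate 3, 678 without mCK-hLPL_REL replicate 2, 776 without mCK-hLPL_WLM replicate 2, 778 without mCK-hLPL_WLM replicate 5 and 796 without mCK-hLPL_REL replicate 3. Erythroid markers were higher in REL in wild type (median 1.14) and in mCK-hLPL (1.68), as were fat cell markers in mCK-hLPL (0.52). The covariates can thus also take up refeeding changes. Beyond that, the cause of these differences was not tested.

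With an estimated correlation the lists past the threshold fell from 6 to 0 for genotype in WLM, from 11 to 0 in REL, from 19 to 1 for refeeding in wild type, from 22 to 0 in mCK-hLPL, from 11 to 0 for the interaction and from 9 to 0 for the average. Fry called 5 lists for refeeding in wild type (smallest adjusted p = 0.000255), 10 in mCK-hLPL (smallest adjusted p = 0.000162) and 0 in each other contrast. For genotype in WLM the fit without lymph node libraries gave 12 and the fat cell covariate 3; leaving out 1 library gave 4 to 14, with 14 without WT_WLM replicate 2 and 10 without WT_WLM replicate 4 or mCK-hLPL_WLM replicate 3. For refeeding in mCK-hLPL the red cell covariate gave 9. For the interaction the fit without lymph node libraries gave 5 and the fat cell covariate 6; leaving out 1 library gave 6 to 18, with 6 without WT_REL replicate 1, 7 without WT_WLM replicate 5 or mCK-hLPL_REL replicate 2, 17 without mCK-hLPL_WLM replicate 1 and 18 without mCK-hLPL_REL replicate 1. For the average the block gave 14 and the fit without liver libraries 15. The correlation across genes of the refeeding changes (0.594) was 0.278 with the block and 0.269 for the same 17 libraries without it. With no low-count filter it was 0.187, over a wider set that holds every row with a count in any library. The cause was not tested.

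The sign of these log2 values changed; apart from the called genes given last, none was past the threshold to begin with. For genotype in WLM, Ppargc1a was at 0.04 without lymph node libraries and from -0.09 to 0.04 with 1 library left out. Cd36 was at -0.02 with quantile normalization and without lymph node libraries, 0 with voom and TMM and with the block, -0.01 with the red cell covariate, and from -0.06 to 0.06 with 1 library left out. Angptl4 was at 0.02 with library weights, 0.29 without lymph node libraries, 0.07 with the fat cell covariate, and from -0.35 to 0.05 with 1 left out. Sln was at -0.07, -0.16 and -0.04 in the same settings, and from -0.18 to 0.21. For genotype in REL, Pdk4 was at -0.24 without liver libraries and from -0.06 to 0.67 with 1 left out. Ucp3 was at -0.01 with library weights, -0.36 without liver libraries, and from -0.09 to 0.47. Sln was at 0.1 with the block and from -0.21 to 0.07.

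For refeeding in wild type, Lpl was at -0.15 with the block, -0.12 for the same 17 libraries without it, 0 without liver libraries, -0.04 with the fat cell covariate, and from -0.01 to 0.17 with 1 left out. Ppard was at 0.03 with the block. Ppargc1a was at 0.01 with library weights and with 17 libraries and no block, 0.05 without lymph node libraries, and from -0.07 to 0.07 with 1 left out. Hbb-bt was at -0.12 with the red cell covariate. In mCK-hLPL, Lpl was at -0.05 with the fat cell covariate. For the interaction, Lpl was at -0.01 with the fat cell covariate and from -0.02 to 0.16 with 1 left out, Ppara at 0.08 without liver libraries and from -0.2 to 0.08, Ucp3 at -0.03 without liver libraries, and Sln at 0.06 with the block and without lymph node libraries and from -0.31 to 0.09. For the average over phases, Pdk4 was at 0.06 with quantile normalization and with 17 libraries and no block, 0.04 with voom and TMM, 0.1 without lymph node libraries, 0.01 with the fat and 0.24 with the red cell covariate, and from -0.18 to 0.18 with 1 left out. Ucp3 was at 0.08 without lymph node libraries, 0.13 with the red cell covariate, and from -0.21 to 0.07. Sln was at 0.07 with the block and from -0.14 to 0.06, Angptl4 from -0.03 to 0.22 and Alas2 at 0 with the red cell covariate. The called genes that changed sign were in refeeding in mCK-hLPL: Hbb-bt at -0.02 and Alas2 at -0.19 with the red cell covariate, which holds both genes' own signal, and Des at 0.03 with quantile normalization. Except for that covariate, the cause was not tested.

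The other single-gene values are counted here. For genes named in the genotype comparison in WLM, 902 of 966 values kept direction and side of the threshold; 1274 of 1296 did in REL, 2924 of 3541 for refeeding in wild type, 3389 of 3984 in mCK-hLPL, 1264 of 1282 for the interaction and 1411 of 1573 for the average. The exact test of Lpl and the other single genes passes only if at least 3 of its 18 tests do, since its smallest p is 0.00794, so its settings say nothing about stability.

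The replicate number was tested as a pair label. Over 21 pairs of the same number in different groups, correlations of residuals ran from -0.356 to 0.211 with a mean of -0.006, against 0.003 for other pairs, and 2 of 17 numbered libraries had their own number as best partner. The numbers are therefore not read as pairs. The planned filter on log2 values was not run, since it does not apply to counts, nor was the exact test within replicate blocks.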

Other observations

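All tests and lists here were chosen after the results were seen.

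Several mitochondrial enzymes that break down branched-chain amino acids, propionate and ketone bodies were lower in mCK-hLPL averaged over phases. Pcca was at 24.3 ± 1.55 CPM in WT_WLM (SD, n = 5) and 19.2 ± 1.95 CPM in mCK-hLPL_WLM (SD, n = 5), and at 24.1 ± 0.412 CPM in WT_REL (SD, n = 4) and 18.5 ± 1.05 CPM in mCK-hLPL_REL (SD, n = 5), a mean log2 difference of -0.36 (edgeR adjusted p = 0.00165). Mmut was at -0.27 (adjusted p = 0.0177), Ivd at -0.38 (adjusted p = 0.0209) and Oxct1 at -0.46 (adjusted p = 0.00298). In a list of 23 such genes, 4 were lower and none higher. Pcca and Mmut were named because of their values. A hypothesis is that the pathway falls as a whole. Without Pcca, Mmut, Ivd, Acadsb, Dbt and Oxct1, the other 17 genes had a median of -0.03 in WLM (camera p = 0.269 with an estimated correlation) and -0.12 in REL (p = 0.0308), so a fall shared beyond the genes that prompted it stays open. The phases are not shown to differ: for all 23 genes the interaction had camera p = 0.36 with an estimated correlation. Fewer mitochondrial transcripts of every kind would lower oxidative phosphorylation genes alike; the score of the pathway was lower by more than that of oxidative phosphorylation, a difference of -0.16 (exact permutation p = 0.0135). That score holds the genes that prompted the list. Without them the difference was -0.1 (exact permutation p = 0.0935), so the 2 accounts cannot be told apart here. The score of the 17 genes alone differed by -0.09 (exact permutation p = 0.0175) and that of oxidative phosphorylation by 0.01 (exact permutation p = 0.903).

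Liver transcripts in the added list had a median change with refeeding of 1.78 in wild type and 2.38 in mCK-hLPL on the log2 scale, with no gene past the threshold over all genes. Without WT_REL replicate B the wild-type median was -1.76. In mCK-hLPL the median was 1.14 without REL replicate 5 and 4.03 without WLM replicate 4, and -1.64 without the 3 libraries with most liver transcripts. Lymph node transcripts had medians of -5.57 and -2.81, likewise with no gene past it over all genes, and with 9 of 9 lower in wild type when adjusted over the list alone. In mCK-hLPL the median was 0.7 without WLM replicate 3, over the 4 members still tested. In wild type it was -4.69 without WLM replicate 1 and -4.47 without WLM replicate 5, over 4 members each, and -0.73 over 3 members without all 3 of these libraries.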
